A study of Homo sapiens with 10 samples.

How the data were processed

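Expression was measured by RNA sequencing of 10 libraries from cultures labelled SH-SY5Y, 5 with control siRNA and 5 with WDFY3 siRNA. Per the labels' protocols, total RNA was extracted with Trizol and columns, 500 ng entered a TruSeq v2 library preparation, and siRNA was delivered by electroporation. The deposited file gives raw gene counts, whole numbers per gene symbol and library, which the authors had not normalized as far as the values show. The build GRCh38 and the tool DESeq2 are named in the submitters' processing notes; the aligner, the counting tool and its strand setting are not given in the sources used here, so counts of overlapping, antisense and near-identical genes are uncertain. Groups and passage labels were taken from the sample descriptions, and each column name matched 1 description. The titles give the passages of the control libraries as 8 (p81 and p83), 9 (p91), 11 (p111) and 10 (p101), and the same for the knockdown libraries except for p101, where the title says 19. The growth protocol gives a passage limit of 15, which a passage of 19 would exceed. Nothing states whether libraries of a group came from separately grown and transfected cultures beyond their passage labels, so p-values measure the spread between these libraries, which may be partly technical.

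Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr by group, robust quasi-likelihood fit, F-test, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. CPM values are counts scaled to the library total, and depth floors are 3 counts; they cover counting error only. Gene lists (34, fixed with the design before the data were examined) were tested with camera of limma 3.58.1 on the same fit, with a preset correlation of 0.01, with an estimated correlation and with fry; a list entered with at least 5 tested members, which 31 did. Symbols of newer nomenclature were matched to the table through RefSeq synonyms. The 13 mitochondrially encoded protein genes had no row under their symbols, so that list and the composition measure built on it are not analysed here, and 4 of 5 planned composition measures were tested. The genes named in the text follow a rule set beforehand: WDFY3; genes past the threshold with a mean of at least 5 CPM and the same sign in all 5 labels (none qualified); members of each list with the smallest p, 2 for lists that did not pass and up to 4 for lists that did; and the WDFY and BEACH relatives. Other genes are said to have been named after their values were seen. Coordinates are those of the RefSeq annotation of GRCh38.

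The passage labels may mark pairs, because a control and a knockdown library share each label. The protocol also says that a single collection of cells was divided into the experimental groups. The title of knockdown p101 disagrees with such a pairing. Deviations from the group means correlated at 0.50, 0.56 and 0.48 within p91, p111 and p83, and at -0.71 and -0.56 within p81 and p101, which each hold a library that stands apart. Each group mean includes such a library, which shifts the deviations of the other libraries the same way. These correlations therefore cannot show pairing. Among the 8 other libraries the 3 complete pairs correlated at 0.09, 0.04 and 0.03. The main fits and the permutation tests took no account of the labels, and the fit with the label as replicate block was an alternative.

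Alternatives set beforehand were RLE and upper-quartile factors, no filter beyond 1 count, a mean of at least 5 CPM, the replicate block, cyclic loess with limma-voom and the block, each library or label left out, DESeq2 1.42.0, limma-voom, a log2 fold change of at least 0.5 and an adjusted p of 0.1. Added after the data were examined were the 8 libraries without control p101 and knockdown p81, the 3 complete pairs, limma-voom with sample quality weights, removal of ribosomal RNA genes, removal of a GC trend, and, in the 8 libraries, a block for the split with the most calls. For the GC trend, the deviation of log2 CPM from the mean over libraries was fitted in each library by a natural spline with 4 degrees of freedom in the GC percent of the longest GENCODE transcript, and the fit entered edgeR as an offset; 13344 of 14280 tested genes had a GC value.

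The procedure was tested on simulated counts for the 14280 tested genes with 200 changed genes. At the spread of all 10 libraries it recovered 0% of genes changed by 0.5, 13.4% by 1 and 87.9% by 2 on the log2 scale, with 1 false call. At the spread of the 8 libraries (14285 genes) it recovered 59.7%, 98.5% and 100% with 12 false calls. With a simulated GC trend in the 8 libraries, 13.4% of the changes of 0.5 were recovered before and 71.6% after its removal, with 0 and 10 false calls. That trend was built from the same GC values that the removal uses, so this does not measure a gain in the real libraries. Other changed genes were drawn there, so 71.6% cannot be set against 59.7%. A simulated list of 40 genes shifted by 0.3 had a camera p of 1.4e-08 at the spread of all 10 libraries, and 4% of 200 unshifted lists had a p under 0.05. Simulated genes were drawn independently of each other, so these values do not cover lists of correlated genes. The S phase list, for example, had an estimated correlation of 0.97 over the 10 libraries. Simulated spread was also even over libraries. In the real data the biological coefficient of variation was 0.42 over all 10 libraries and 0.12 without control p101 and knockdown p81. The recovery at the spread of all 10 libraries is therefore only a rough guide to the real fit.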

Results

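WDFY3, also called ALFY, is a large BEACH-domain protein known as an adaptor of selective autophagy. RNA was sequenced from undifferentiated cultures labelled SH-SY5Y, a human neuroblastoma line, after transfection with control siRNA or with a pool of 4 siRNAs against WDFY3 at 10 nM. There were 5 libraries in each group, named here by the passage labels p81, p83, p91, p111 and p101 that occur once per group. The table held gene counts for 29744 symbols, of which 9114 had no count in any library. Total counts ran from 26969710 in knockdown p101 to 42315699 in control p111, so that 3 counts correspond to between 0.0709 and 0.111 CPM, the counts of a gene scaled to the library total. The series title names proliferation and differentiation after loss of WDFY3 as its subject, and the comparison asks which transcripts differ between knockdown and control cells.

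WDFY3 (GRCh38 chromosome 4, 84669597 to 84966690) was lower in every knockdown library than in every control library. The 5 control libraries had 56.4 (p81), 53.6 (p83), 56.7 (p91), 54.9 (p111) and 96.6 CPM (p101), with a mean of 63.6 ± 18.4 CPM (SD, n = 5). The 5 knockdown libraries had 29.3 (p81), 31.4 (p83), 33.6 (p91), 40.2 (p111) and 35.9 CPM (p101), with a mean of 34.1 ± 4.19 CPM (SD, n = 5). Within a passage label the knockdown library held between 37.1% (p101) and 73.2% (p111) of its control. Labels p101 and p81 (51.9%) each hold a library that stood apart from the others, as described below. The remaining labels had 58.6% (p83), 59.3% (p91) and 73.2% (p111). An exact two-sided permutation test of log2 CPM gave p = 0.0079, the smallest that reassigning the libraries can give. In edgeR's quasi-likelihood fit over all genes the log2 fold change was -0.94 ± 0.19 (SE), with an unadjusted p of 0.00056 and a Benjamini-Hochberg adjusted p of 1.00. Without control p101 and knockdown p81, an alternative chosen after the data were examined, it was -0.67 ± 0.09 (SE) with an edgeR adjusted p of 0.019. Leaving out one further library ended that call in 4 of 8 fits, with edgeR adjusted p of 0.058 without control p81, 0.096 without control p91, 0.069 without control p111 and 0.084 without knockdown p91, and log2 fold changes of -0.66, -0.67, -0.67 and -0.65.

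**Figure D1:**
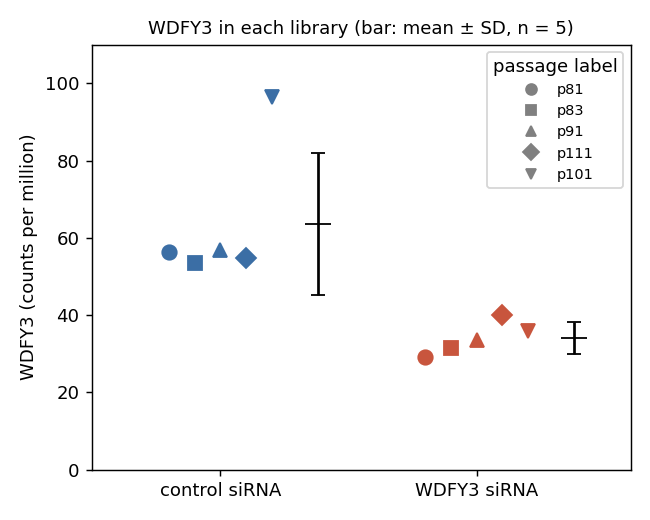
WDFY3 in CPM (vertical axis) in each library of the control siRNA and WDFY3 siRNA groups; symbols mark the passage label and the bars show mean ± SD of 5 libraries. All 5 knockdown libraries lie between 29.3 and 40.2 CPM, and the controls between 53.6 and 96.6 CPM.

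Control p101 and knockdown p81, which belong to different groups and different passage labels, stood apart from the other 8 libraries. The library numbers in the titles are 1, 5, 9, 13 and 17 for controls and 2, 6, 10, 14 and 18 for knockdowns, and libraries with the numbers between them are not analysed here. Across the tested genes their Spearman correlations with those 8 ranged from 0.841 to 0.848 for control p101 and from 0.888 to 0.898 for knockdown p81, against 0.97 with each other and 0.986 to 0.996 among the 8. The first principal component, with 78.3% of the variance, separated these libraries from the rest. Of 52 genes of the G2 and M phase list, 51 were below the range of the other 8 in both. TOP2A, the topoisomerase that untangles chromosomes in mitosis, had 16.9 CPM in control p101 and 190.9 CPM in knockdown p81, against 892 to 1148 CPM in the others. CENPF, a kinetochore protein, had 12.8 and 105 CPM against 804 to 997 CPM. COL3A1, a fibrillar collagen, had 27.8 and 64.3 CPM against 4713 to 6388 CPM. CPS1, the first enzyme of the urea cycle, had 103 and 486 CPM against 4747 to 5638 CPM. AXIN2, a feedback inhibitor of Wnt signalling, had 0.0636 and 0.442 CPM against 43.6 to 72.2 CPM. Of 30 genes of the unfolded protein and integrated stress response list, 23 were above that range in both and 2 below it in both, while of 20 cytosolic chaperones 3 were above and 9 below in both. The endoplasmic reticulum chaperone HSPA5 had 5512 and 5322 CPM against 913 to 1272 CPM. DDIT3, a transcription factor of that response, had 103 and 99.996 CPM against 6.18 to 8.38 CPM. FTH1, the ferritin heavy chain that stores iron, had 20662 and 12760 CPM against 2601 to 3052 CPM. MAP2, a microtubule-binding protein of neuronal dendrites, had 247 and 159 CPM against 7.12 to 25.7 CPM. These genes and lists were singled out after their values were seen, and no test was made of these libraries against the others.

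**Figure D2:**
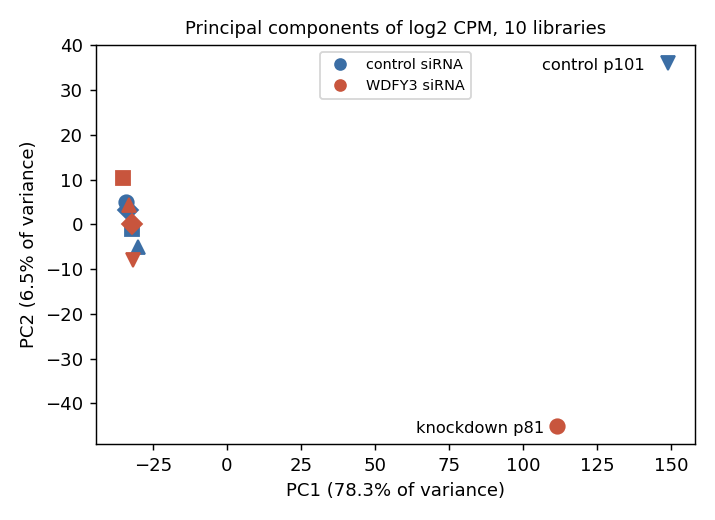
Principal components of log2 CPM over the tested genes, with one point per library coloured by siRNA; the axes give the share of variance. Control p101 and knockdown p81 lie far from the other 8 libraries along the first component, which holds 78.3% of the variance.

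Many transcripts that mark sympathetic neuroblasts were close to the detection floor. Of 30 genes in the noradrenergic neuroblastoma list, 20 were under 0.5 CPM in all 10 libraries, while 7 had a median of 1 CPM or more and KLF13 reached 294 CPM. HAND2, a transcription factor of sympathetic neurons, reached at most 0.220 CPM, and the catecholamine enzymes TH and DBH at most 0.191 and 0.0628 CPM. Of 36 genes in the mesenchymal neuroblastoma list, 33 had a median of 1 CPM or more, and among the 8 libraries VIM, an intermediate filament of mesenchymal cells, ranged from 733 to 902 CPM. The keratins KRT8 and KRT18, filaments of simple epithelia, ranged from 507 to 750 CPM and from 497 to 692 CPM in those 8; of 10 epithelial markers 6 had a median of 1 CPM or more and 4 a median under 0.5 CPM. Among other cell types, 9 of 12 Schwann and glial markers had a median under 0.5 CPM, as did 6 of the 7 blood cell markers with a row, the exception being CD68. Only 4 and 1 genes of these lists passed the expression filter, so neither was tested as a list. The genes named in this paragraph were picked after their values were seen.

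**Figure D3:**
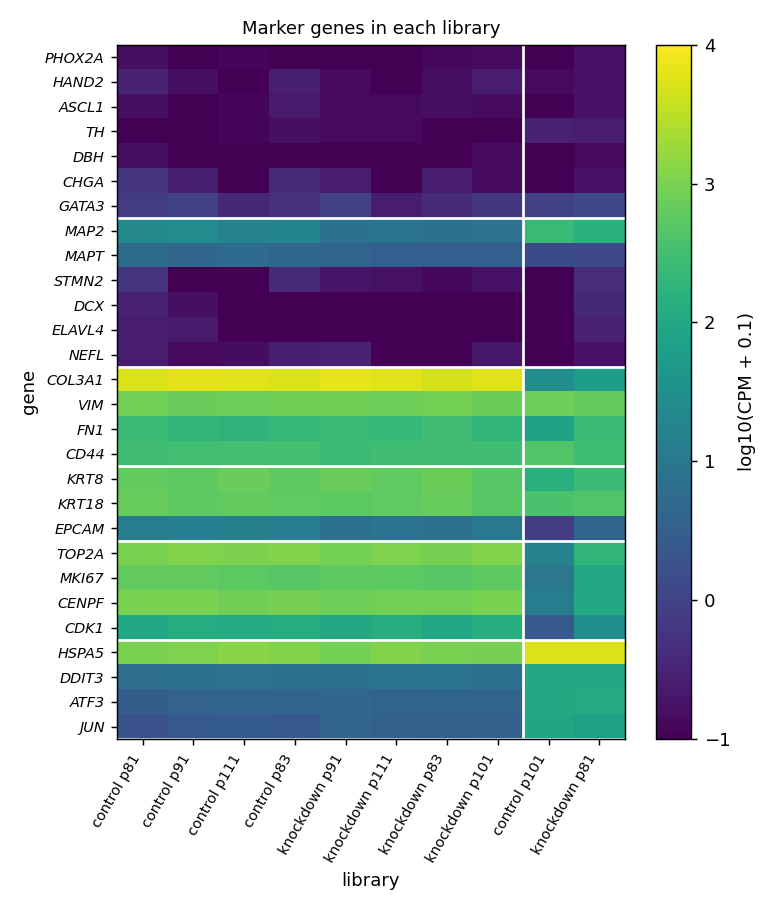
Expression of marker genes (rows) in each library (columns) as log10(CPM + 0.1), grouped from top to bottom as noradrenergic, neuronal, mesenchymal, epithelial, cell division and stress-response genes. The last columns are control p101 and knockdown p81, where TOP2A is 16.9 and 190.9 CPM; HAND2 is at most 0.220 CPM in any library.

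Over all 10 libraries no gene passed an edgeR adjusted p of 0.05 among 14280 tested, and 158 had an unadjusted p under 0.05. DESeq2 and limma-voom also called 0 genes, and limma-voom with sample quality weights, added after the data were examined, called 7. Gene lists fixed beforehand were tested with camera at a preset correlation of 0.01, and 11 of 31 lists passed, 7 towards higher and 4 towards lower values. None of them passed with an estimated correlation. The lysosome list was shifted downward, with 42 of 45 genes lower, a median log2 fold change of -0.22 and a camera adjusted p of 6.2e-15 (adjusted p = 0.073 with an estimated correlation). CTSA, a lysosomal carboxypeptidase, had a log2 fold change of -0.46 ± 0.13 (SE) and was lower in 5 of 5 passage labels (-0.31 ± 0.07 without control p101 and knockdown p81). GLB1, the lysosomal beta-galactosidase, had -0.39 ± 0.11 (SE), and LAMP1, an abundant lysosomal membrane protein, -0.36 ± 0.13 (SE), each lower in 5 of 5 labels. These members were named for their small p in this same fit, so their shared sign adds no independent support. Labels p81 and p101 also each set a library that stands apart against an ordinary one. The interferon response list was also lower, with 24 of 29 genes below control, a median of -0.24 and an adjusted p of 1.0e-06 (adjusted p = 0.18 with an estimated correlation). Its members IFIT2 and ISG20 had log2 fold changes of -0.84 ± 0.32 and -0.64 ± 0.26 (SE). Nuclear genes of oxidative phosphorylation were higher, with 43 of 46 above control, a median of 0.10 and an adjusted p of 4.6e-06 (adjusted p = 0.57 with an estimated correlation). NDUFB8, a subunit of respiratory complex I, had 0.22 ± 0.09 (SE). No member of these 3 lists passed when adjusted over the list alone. Leaving out each library in turn ended none of the 10 calls of the lysosome list (medians -0.26 to -0.15). Without control p101 the interferon median was -0.06 (adjusted p = 0.040) and that of oxidative phosphorylation 0.05 (0.23), while without knockdown p81 they were -0.50 and 0.17.

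The other 8 lists that passed included S phase (median 0.07, adjusted p = 0.00067), G2 and M phase (0.07, 0.0012) and p53 targets (-0.25, 0.00067). With an estimated correlation the adjusted p was 0.75, 0.75 and 0.58. These 3 moved with the libraries that stood apart: without control p101 alone the medians were -0.19, -0.21 and 0.20, and without both libraries -0.03, -0.02 and -0.01 with adjusted p of 0.49, 0.33 and 0.71. MYC targets (median 0.04, adjusted p = 0.037) had -0.04 without both libraries (adjusted p = 0.14). Proteasome genes had a median of 0.09 (adjusted p = 0.0012), cytosolic chaperones 0.09 (0.018), ribosomal proteins 0.06 (0.022) and Wnt pathway components -0.05 (0.025). Their adjusted p with an estimated correlation was 0.58, 0.57, 0.75 and 0.57, and that of MYC targets 0.75. Of the 10 fits that each left out a library, the call was kept in its direction in 8 for S phase, proteasome and chaperones, 7 for G2 and M phase, 9 for p53 targets, 6 for Wnt components, 5 for MYC targets and 4 for ribosomal proteins. In the 11 lists no gene passed when adjusted over the list alone, and among the other 20 only TAGLN, a smooth-muscle actin-binding protein of the fibroblast list, did (log2 fold change 2.04 ± 0.52 SE, and 1.18 ± 0.23 without control p101 and knockdown p81). With the passage label as replicate block 12 lists passed, the added one being the fibroblast list (adjusted p = 0.028). Without the block the fibroblast list had an adjusted p of 0.58 with an estimated correlation and 0.95 with fry; neither was run with the block.

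Among the lists that did not pass were those nearest to the known role of WDFY3. Autophagy core genes had a median of -0.05 (23 of 40 lower, camera adjusted p = 0.32) and selective autophagy receptors -0.11 (20 of 25 lower, adjusted p = 0.069). The WDFY and BEACH relatives had a median of -0.16 (7 of 8 lower, adjusted p = 0.24); the log2 fold changes were -0.05 ± 0.14 for WDFY1, -0.22 ± 0.56 for WDFY2, -0.11 ± 0.11 for LRBA and -0.37 ± 0.53 (SE) for NBEA. Without control p101 and knockdown p81 these 3 lists had medians of 0.016 (25 of 40 higher), -0.0054 (14 of 25 lower) and 0.010 (5 of 8 higher), with adjusted p of 0.56, 0.63 and 0.73, and WDFY2 and NBEA had 0.01 ± 0.12 and -0.15 ± 0.13 (SE). Cyclins, CDKs and CDK inhibitors (0.05, 0.40), microcephaly genes (0.03, 0.16), macrocephaly and overgrowth genes (-0.02, 0.91) and high-confidence autism genes (-0.05, 0.12) did not pass, each pair being the median and the adjusted p. Neural progenitor markers (-0.08, 0.084), neuronal cytoskeleton and growth genes (0.07, 0.26) and synapse genes (0.05, 0.84) did not pass either. Among identity lists the values were -0.17 and 0.11 for noradrenergic, -0.07 and 0.24 for mesenchymal, 0.04 and 0.058 for fibroblast, and -0.02 and 0.92 for epithelial markers. Wnt target genes had -0.14 and 0.061, retinoic acid response genes -0.03 and 0.24, and immediate early genes -0.16 and 0.11. The unfolded protein and integrated stress response list had -0.08 and 0.39, glycolysis and hypoxia 0.01 and 0.97, and cholesterol synthesis 0.11 and 0.37. The median and the mean or test differed in sign for the cyclin list (mean -0.06), the synapse list (mean -0.08) and the glycolysis list (mean -0.03, tested direction down). In the 8 libraries the medians of microcephaly genes (-0.026), macrocephaly and overgrowth genes (0.028) and synapse genes (-0.014) also had the other sign, and those of noradrenergic (-0.082), mesenchymal (-0.017), immediate early (-0.057) and autism genes (-0.0059) were nearer 0. The median of the cyclin list was -1.4e-05 there. Medians of fibroblast (0.16), retinoic acid (-0.078), epithelial (-0.032), neuronal cytoskeleton (0.10) and glycolysis genes (0.021) lay farther from 0 than over all libraries.

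With control p101 and knockdown p81 left out, a choice made after the data were examined, 15 of 14285 genes differed between 4 control and 4 knockdown libraries, 3 higher and 12 lower. The biological coefficient of variation was 0.12, against 0.42 over all 10. MAP2 (chromosome 2, 209424047 to 209734112) fell from 20.9 ± 3.998 to 7.67 ± 0.485 CPM (SD, n = 4), a log2 fold change of -1.47 ± 0.13 (SE, edgeR adjusted p = 0.0011). EPCAM, an epithelial adhesion molecule, fell from 13.96 ± 1.13 to 7.96 ± 1.33 CPM (-0.84 ± 0.12, edgeR adjusted p = 0.028). NRP1, a co-receptor for semaphorins and VEGF, fell by 0.60 on the log2 scale (edgeR adjusted p = 0.028), and NEO1, a netrin receptor, by 0.98 (edgeR adjusted p = 0.048). FYN, a Src-family kinase, fell by 0.62, MEGF9 by 0.64, and the carboxypeptidase CPVL by 0.60. PARP14, an interferon-induced ADP-ribosyltransferase, fell by 0.61; IFI30, a lysosomal thiol reductase induced by interferon, by 0.49; and ERAP1, which trims peptides for antigen presentation, by 0.58. WDFY3 and TMEM2 were the remaining genes that fell. MYOCD (chromosome 17, 12665890 to 12768949), a co-activator of smooth-muscle genes, rose from 36.3 ± 5.45 to 81.9 ± 12.4 CPM (1.15 ± 0.13, edgeR adjusted p = 0.0047). SPINK5, a protease inhibitor, rose by 1.17 and TNXB, a matrix glycoprotein, by 1.07. All 15 moved the same way in the 3 passage labels with both libraries. This adds no independent support, since the 15 were called from these same libraries. Apart from WDFY3 and EPCAM they were named after their values were seen. In the 3 complete pairs with the replicate block 29 genes passed, 10 of them among the 15, while NRP1, FYN, IFI30, TMEM2 and NEO1 did not. The largest log2 fold changes among the 29 were -9.54 for GDF1 and 9.45 for PHOSPHO2-KLHL23, also named after their values were seen. Like PPAN-P2RY11 and TMEM256-PLSCR3 among the 29, the latter symbol joins names of separate genes, and counts of overlapping genes are uncertain here. Neither GDF1 nor PHOSPHO2-KLHL23 was among the 38 genes with an edgeR adjusted p under 0.1 in the 8 libraries. When one further library was left out, 3 genes passed without control p81, 2 without control p91, 3 without control p111 and 4 without control p83, of which 2, 2, 3 and 3 were among the 15. Without knockdown p91, p111, p83 or p101, 2, 4, 10 or 18 passed, of which 2, 4, 6 and 13 were among the 15. DESeq2 called 131 genes in the same libraries.

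Libraries also differed in how expression followed the GC content of the transcripts, in a pattern that crossed the siRNA groups. After that trend was taken out of each of the 8 libraries, 149 genes differed, 38 higher and the rest lower, and these included all 15 above. This count rests on choices made after the data were examined: the libraries left out, and the removal of the trend, made once a split of the 8 libraries across the groups had been seen to call 1996 genes and a fit with that split as a block to call 94. Over all 10 libraries the removal left 0 genes in edgeR. Without control p81, p91, p111 or p83 the count was 76, 45, 67 or 48 genes, and without knockdown p91, p111, p83 or p101 it was 50, 72, 249 or 63. The genes that fell included the lysosomal proteins CTSD (-0.49 ± 0.08 SE, edgeR adjusted p = 0.019), CTSZ (-0.27 ± 0.05), CTSA (-0.33 ± 0.07) and PSAP (-0.27 ± 0.06). GRN, the progranulin precursor, fell by 0.41 and GPNMB, a glycoprotein of lysosomes and melanosomes, by 0.61. The interferon-linked genes OAS3, PARP10, PARP12, LGALS3BP and HLA-B fell by 0.72, 0.67, 0.48, 0.47 and 0.33. MAPT, which encodes tau, fell by 0.70 and NOTUM, a secreted Wnt inhibitor, by 0.39. The neuronal cytoskeleton and growth list, which holds MAPT and MAP2, had 12 of 18 genes higher before and after the removal. Its medians were 0.10 and 0.077 (camera adjusted p = 0.77 and 0.84). Among genes that rose, KRT17 gained 0.67, LGALS1 0.37 and the cholesterol enzyme MVD 0.42 on the log2 scale. WDFY3 had -0.66 ± 0.07 (SE, edgeR adjusted p = 0.00081). Apart from WDFY3, CTSA and MVD, these genes were named after their values were seen.

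In the 8 libraries 9 of 31 lists passed with the preset correlation, and 0 with an estimated one. The lysosome list had a median of -0.14 with 38 of 45 genes lower (camera adjusted p = 7.8e-11; adjusted p = 0.27 with an estimated correlation), and 9 members passed when adjusted over the list alone. The interferon list had -0.30 with 24 of 29 lower (5.3e-08; adjusted p = 0.27 with an estimated correlation), and 4 members passed over the list alone. Oxidative phosphorylation had 0.10 with 43 of 46 higher (1.3e-06; adjusted p = 0.57 with an estimated correlation). Cholesterol synthesis had 0.10 with 20 of 25 higher (0.00080), ribosomal proteins 0.07 (0.0024) and proteasome 0.06 (0.012). Wnt target genes had -0.14 with 11 of 17 lower (0.0040), Wnt pathway components -0.07 (0.022) and the unfolded protein and integrated stress response -0.08 (0.025). With an estimated correlation the adjusted p was 0.43 for Wnt targets and 0.74 for each of the other 5 lists. Calls of the lysosome, interferon and oxidative phosphorylation lists were kept in all 8 fits that left out one further library. Without knockdown p101 the medians of the stress response list and Wnt components were -0.011 and -0.013 (adjusted p = 0.59 for both), and proteasome and Wnt targets (median -0.084) had an adjusted p of 0.053 each. Without control p111 the stress response list (-0.035) and Wnt components had 0.62 and 0.15, and without control p83 the stress response list had 0.051. Without control p81 the proteasome list had 0.18 and Wnt components a median of -0.042 (0.027), and without knockdown p111 the proteasome list had 0.075. Cholesterol synthesis had 0.041 (0.092) without knockdown p83, and ribosomal proteins 0.036 (0.16) without control p91. In the 3 complete pairs with the replicate block, a fit that also leaves out control p81 and knockdown p101, proteasome (adjusted p = 0.67), Wnt components (0.67), ribosomal proteins (0.087) and Wnt targets (0.065) no longer passed. In that fit S phase (median -0.08, adjusted p = 0.013) and G2 and M phase (-0.09, 0.0069) passed towards lower values, and glycolysis and hypoxia (0.08, 0.026) towards higher values. Without knockdown p101 alone and with no block, S phase (0.022) and G2 and M phase (0.034) also passed. Glycolysis and hypoxia passed towards higher values without control p83 (0.10, 0.028) and towards lower values without knockdown p83 (-0.10, 0.0051). An estimated correlation was not run in the 3 pairs or with a further library left out. In the 8 libraries it gave a camera adjusted p of 0.80 for S phase, 0.80 for G2 and M phase and 0.91 for glycolysis and hypoxia. Other lists past the threshold with a further library left out, but not in the 8, were MYC targets (without control p91 or knockdown p83, adjusted p = 0.030 and 0.042), fibroblast markers (the same libraries, 0.0098 and 0.0039), chaperones (without control p83, knockdown p91 or knockdown p83, 0.038, 0.039 and 0.042), neural progenitor markers (without knockdown p91, 0.028) and immediate early genes (without knockdown p83, 0.0074). With the GC trend removed from the 8 libraries, 10 lists passed, the added one being MYC targets (median -0.042, adjusted p = 0.046), and with an estimated correlation none passed (adjusted p of 0.24 or more, and 0.75 for MYC targets).

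**Figure D4:**
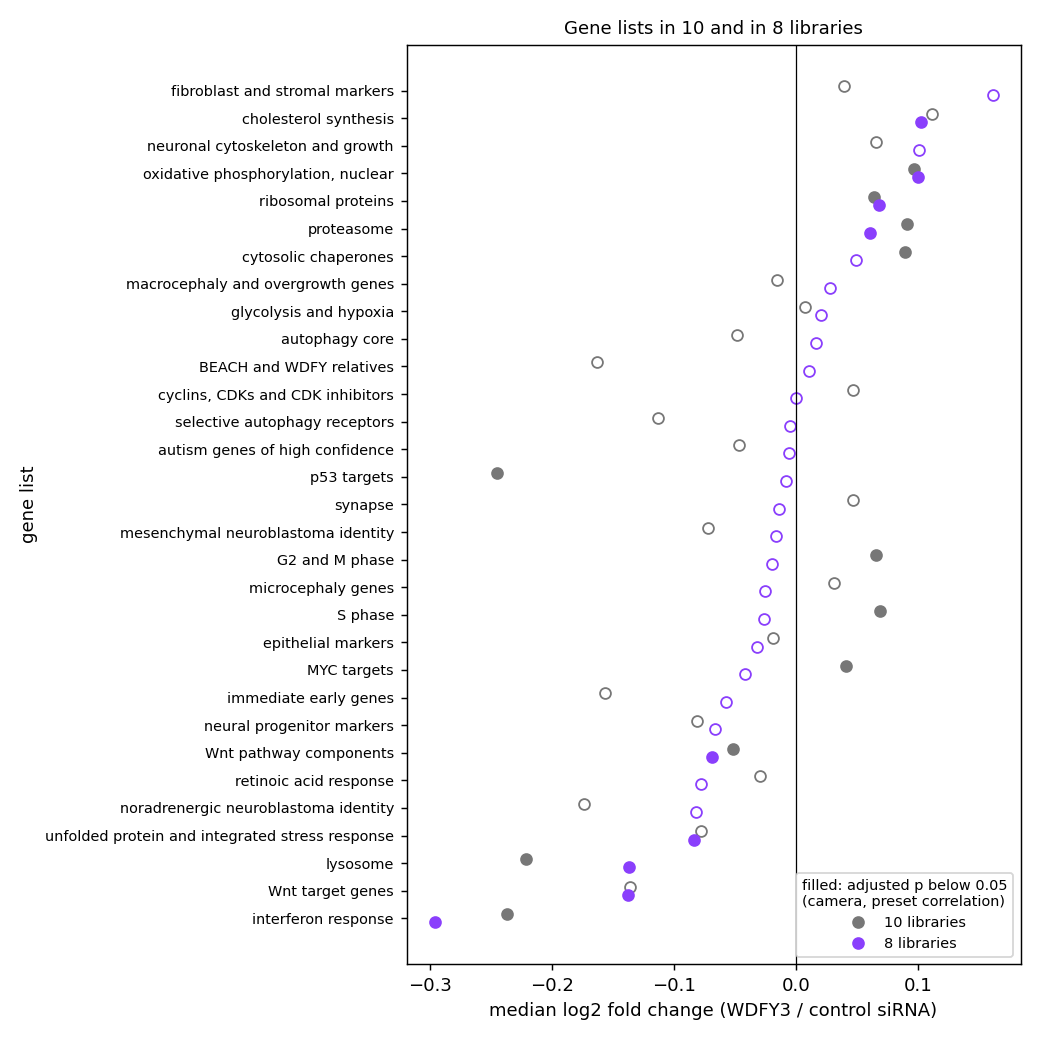
Median log2 fold change (horizontal axis) of each fixed gene list in all 10 libraries and in the 8 left without control p101 and knockdown p81; filled points have a camera adjusted p below 0.05 with the preset correlation. The lysosome list lies at -0.22 and -0.14 and the interferon list at -0.24 and -0.30, while S phase moves from 0.07 to -0.03.

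Over all 10 libraries, library composition did not differ detectably between the groups. Exact two-sided permutation tests over every reassignment of the libraries gave p = 0.21 for total counts, 0.60 for detected genes (17419 ± 110.1 in controls and 17364 ± 197 in knockdowns, SD, n = 5), 0.46 for the share of ribosomal protein genes and 0.52 for the share of the 100 most abundant genes, each with an adjusted p of 0.60. The share of ribosomal RNA, added after the data were examined, was 2.44% ± 0.489 in controls and 2.24% ± 0.375 in knockdowns (SD, n = 5, exact permutation p = 0.49). Composition was not tested in the 8 libraries. There the ribosomal protein share ran from 4.55% to 4.99% in controls and from 4.91% to 5.27% in knockdowns. It was 3.32% in control p101 and 3.69% in knockdown p81.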

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

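Apart from the GC test of the libraries that stand apart, the GC test of the lysosome list and the counts of splits, the tests in this part were chosen after the results were seen, as were, among those counts, the ones for lists without the GC trend, for splits that part pairs and for the sides of the libraries that stand apart; the count for the smallest list p was added once that p was known, but before it was counted over splits. Values far from the rest of their group were sought with Dixon's criterion in groups of 5, which chance meets in about 1 of 20 groups. WDFY3 in control p101 (96.6 CPM), the total count of control p111 (42.3 M counts), the ribosomal protein share of control p101 (3.32%) and of knockdown p81 (3.69%), and the share of the 100 most abundant genes in knockdown p81 (18.3%) lay far from the others. Of 86 named genes besides WDFY3, 27 had control p101 and 16 had knockdown p81 far from its group. FUNDC1 (24.0 CPM), TIPIN (28.8 CPM) and RARB (0.964 CPM) were set apart in knockdown p101, and TSC2 (157 CPM) in knockdown p91. Over all 14280 tested genes, control p101 was set apart at 38.5% and knockdown p81 at 25.4%, and no other library at more than 0.518%.

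Control p101 and knockdown p81 differ from the other 8 libraries in many genes at ordinary depth. An exchange of labels between these libraries is argued against by WDFY3, which was 3.30 times higher in control p101 than in knockdown p81, each on its own group's side. A bias of GC content or transcript length explained at most 3.13% of the variance of their deviations over genes. HOX genes differ between cell lines of different body regions. Of 39, 15 had a median of at least 5 CPM in the other 8 libraries and 10 a median under 0.5 CPM. A gene of the first kind was discordant if under 0.5 CPM in both libraries that stand apart. A gene of the second kind was discordant if at 5 CPM or more in both. By this rule 0 were discordant, and the remaining HOX genes could not count. The median deviation of an autosome departed from that of all genes by up to 0.22 on the log2 scale. Another culture state, such as arrest under stress, a library from another condition of the same project (the library numbers in the titles leave gaps) and an outside library of other cells cannot be told apart, since the labels record no difference in handling and libraries with the missing numbers are not analysed here; no biological explanation was tested, and values over all 10 libraries rest on these libraries being what their labels say.

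The second pattern is the low level of many sympathetic neuroblast transcripts in cultures labelled SH-SY5Y. Counts out of register with the symbols are argued against by the ribosomal protein genes, of which 52 of 52 had a median of 100 CPM or more. Too little depth is argued against by a floor of at most 0.111 CPM. A mesenchymal state of the named line and another cell line cannot be told apart: 33 of 36 mesenchymal genes had a median of 1 CPM or more, but many adherent lines express them, and no library of known identity was part of the comparison.

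The third pattern is the lower lysosome list after WDFY3 siRNA. With a trend in GC content and transcript length removed its median stayed at -0.22 (bootstrap 95% interval -0.24 to -0.17 over genes). Fold changes over the 10 libraries hardly followed GC content (Spearman correlation 0.0023 across genes), so there was little GC trend to remove. In the 8 libraries that correlation was 0.11, and the list median without the trend was -0.15 (-0.18 to -0.11). This argues against that trend as the whole cause. Without the libraries that stand apart the median was -0.14 (-0.21 to -0.09), so a lower median was also seen without them. These intervals resample genes as if independent, while the estimated correlation between genes of the list was 0.13 in the 8 libraries. They do not measure the spread between libraries, and so cannot show that the remaining shift exceeds it. Of the 35 splits of the 8 libraries, 1, the real one, gave a median as far from 0 (0.14, against 0.11 for the highest other), but the list was taken up for its small p, its adjusted p there was 0.27 with an estimated correlation and 0.15 with fry, and 9 of 35 splits gave some list with a camera p as small (11.6 as -log10 p, against 33.3 for the highest other), so chance cannot be excluded. An effect of the siRNA pool on other targets stays open, since no second pool was used, and a lower lysosome list as an effect of WDFY3 loss is a hypothesis.

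Other splits of the libraries show how far the counts can be read. Over the 10 libraries the splits decide nothing about genes, since the real count is 0, which all 100 drawn splits reach (highest other 2). For lists, 51 of the 100 gave as many as the real 11 (highest other 17), so chance cannot be excluded. These were all 40 splits with control p101 and knockdown p81 on the same side (11 to 17 lists) and 11 of the 60 with them on different sides, as in the real split. Among the drawn splits that part all 5 labels, 4 of 9 gave as many lists. Over the 8 libraries, 2 of 35 splits, and 2 of the 8 that part the 3 complete pairs, gave at least 15 genes, and 7 of 35 gave at least 9 lists (highest other 10), so chance cannot be excluded. The other split called 1996 genes, which points to a structure of the samples. It set control p81, control p111, knockdown p91 and knockdown p83 against the remaining libraries, and across genes, which are not independent replicates, its fold changes followed GC content with a Spearman correlation of 0.79, against 0.11 for the siRNA comparison. Once the GC trend was removed, 1 of 35 splits, the real one, gave 149 genes, and the highest other gave 10, but the removal was chosen because of the split that had called more genes than the real one, so this count does not exclude chance. For lists without the trend, 3 of 35 gave as many as the real 10 (highest other 11), so chance cannot be excluded. Among the 8 splits that part the 3 complete pairs, the real one gave 149 genes without the trend, against 1 for the highest other, and a lysosome median of 0.14 against 0.09. With the trend left in, the lysosome median was 0.14 against 0.10 and the smallest list p 11.6 against 6.03 as -log10 p. For these values 8 splits are too few for a share under 0.05.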

How the results depend on the processing

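The GC, 8-library, complete-pair, quality-weight, split-block and ribosomal RNA alternatives were chosen after the results were seen. WDFY3 kept its direction and an unadjusted p under 0.05 in all 30 alternatives to the fit of 10 libraries (-1.01 to -0.63; adjusted p from 0.0123 to 1.00, under 0.05 in 3). Further alternatives within the 8 libraries gave -0.74 to -0.62, with adjusted p from 6.0e-10 to 0.096. The count of 0 changed genes in edgeR became 15 in the 8 libraries, 29 in the 3 complete pairs with the replicate block and 7 with quality weights. The 11 lists became 0 with an estimated correlation, 0 with fry and 6 with quality weights, and leaving out one library gave 5 (without knockdown p101) to 16 (without knockdown p81). In the 8 libraries the 15 genes became 131 with DESeq2, 29 with the replicate block over 3 pairs, 94 with the block for the split with the most calls, 149 without the GC trend, and 2 to 18 when one library was left out; the 9 lists became 0 with an estimated correlation and 0 with fry.

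Some lists that passed turned direction. Without label p101 in both groups the medians were -0.27 for S phase, -0.31 for G2 and M phase, 0.29 for p53 targets, -0.027 for chaperones, -0.032 for ribosomal proteins and -0.13 for MYC targets; with the replicate block as well they were -0.35, -0.43, 0.25, -0.032, -0.039 and -0.14. With the block and without p81 the proteasome had -0.015. In the 8 libraries S phase, G2 and M phase and MYC targets had -0.026, -0.020 and -0.042, in the 3 pairs -0.077, -0.090 and 0.012 (chaperones -0.038), and with quality weights -0.037, -0.030 and -0.028. Leaving out one library gave -0.19 to 0.26 for S phase, -0.21 to 0.28 for G2 and M phase, -0.63 to 0.20 for p53 targets, 0.011 to 0.15 for ribosomal proteins (tested direction down at the lower end) and -0.091 to 0.14 for MYC targets; each end came without control p101 or without knockdown p81. Beyond fewer libraries, the cause was not tested. With the replicate block in all 10 libraries no call changed besides that of the fibroblast list. At the spread of all 10 libraries changes of 1 on the log2 scale were mostly missed in simulated data. The count of 0 there therefore says little about changes of that size. Simulated spread was even over libraries, unlike the real spread, so those recovery rates are only a rough guide.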
